A study of Mus musculus with 4 samples.

How the data were processed

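Total RNA from mouse liver lysates was measured on 4 single-channel expression arrays, 1 array for each combination of genotype (wildtype or YAP-KO) and time (0 h or 24 h after acetaminophen). Per the labels, the mice were male and fasted, the wildtype animals carried a floxed Yap1 gene, and RNA was extracted with Trizol, labelled with biotin using the GeneChip WT Plus kit and hybridised as a pool of 3 mice per array. The 24 h mice received 300 mg/kg acetaminophen by intraperitoneal injection. The exons deleted in the YAP-KO mice, the Cre driver and the cells in which deletion took place were not given in the sources used here.

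The deposited values were on a log2 scale, as inferred from their range (2.24 to 19.93 over all arrays, with 2 decimals): no label or file header gives the log base, the summarisation, the background correction or the normalization that the authors applied. The 65956 probe sets had array medians of 4.47 (wildtype 0 h), 4.46 (YAP-KO 0 h), 4.32 (wildtype 24 h) and 4.36 (YAP-KO 24 h). The quartiles differed between arrays too, so the probe-set values as they stand do not share one distribution. Whether quantile normalization was applied at an earlier step is not known. No detection call or background level was used here, so genes close to the low end have no known floor. Each array had a highest value shared by many genes (19.86, 19.83, 19.93 and 19.88 in the same order), and 68 genes lay within 0.01 of it on all 4 arrays. Such values were treated as saturated: a difference from a lower value is given as "at least", and none is given between saturated values. Array number limits the precision of every value: with 1 array per group there is no replicate error, and a pool hides the spread between mice.

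Probe sets were named from the platform annotation supplied for the value table. Of them, 31388 carried 1 gene, 1362 carried several and 33206 carried none. Symbols were updated through Entrez identifiers to the mouse RefSeq annotation (GRCm38.p6), which changed 853 of them. No gene value was taken from a probe set with several genes; where such a probe set is described, its readings are given as those of the probe set. For the 423 genes with several probe sets the one with the highest mean over the 4 arrays was taken. Of 30827 named genes, the 18500 with a mean at or above the 40th percentile (4.322) were kept.

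Differences between arrays are log2 differences, in which 1 unit is 2-fold. Genes at or beyond 2-fold were counted for 5 contrasts: 24 h minus 0 h in each genotype, YAP-KO minus wildtype at each time, and the difference between the 24 h responses. These contrasts compare single arrays, have no residual degrees of freedom and carry no p-value. The only test was a limma fit of genotype plus time over the 4 arrays with empirical Bayes moderation, a Benjamini-Hochberg adjusted p under 0.05, and 1 residual degree of freedom, which is the interaction between genotype and time. Genes that respond differently in the genotypes therefore have large errors in this fit. In simulated data for 24 h against 0 h over 18500 genes, with 200 genes changed in each of 20 runs, it recovered 0.2% of those changed by 2 log2 units and 31.9% of those changed by 4, with a median of 2.5 unchanged genes called, and 5.17% of unchanged genes had an unadjusted p under 0.05. The simulated changes were equal in both genotypes, and in the data 3428 genes differed 2-fold in wildtype. These rates are therefore not the power of the fit on the real arrays.

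A total of 32 gene lists (pathways, hepatocyte zones and markers of liver cell types) were fixed before the data were examined. For each, the median difference over measured members was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. Medians outside the central 95% (2.5 to 97.5 percentiles) are described as outside the random range, as a description of these arrays. On simulated lists of 15 genes for YAP-KO against wildtype at 0 h, 6.5% of 200 unshifted lists fell outside that range and 99% of lists shifted by 0.5 lay above it. Of 160 list medians computed, 77 lay outside, where 8 would if every list behaved like its random lists. The random lists were matched on size and mean expression, not on any tendency of list members to vary together. The 160 medians also share arrays and some genes. The 8 is therefore not a chance level for these lists, and the excess over it was not tested. Members of the additive fit were also counted with p adjusted over the list alone.

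Genes were named by a rule fixed before the data were examined: Yap1, Wwtr1, Ccn1, Ccn2, Ccnd1 and Cdkn1a; the 10 highest and 10 lowest differences of each contrast, leaving out predicted and RIKEN genes, olfactory and vomeronasal receptors, immunoglobulin and T cell receptor segments, microRNA, small nucleolar and ribosomal RNA genes; up to 4 members with the largest differences in a described list and members that go against its median by 1.5-fold or more; and the 10 smallest p-values of each additive result. A gene outside this rule is named only where it is said to have been chosen after its values were seen.

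Each result was also computed under settings decided before the data were examined. These were quantile normalization, centring each array on the median of its tested genes, no filter and a 60th percentile filter. They also included the mean of a gene's probe sets, thresholds of 1.5-fold and 4-fold, a variance trend, robust moderation and an adjusted p under 0.1. Other settings were added after seeing the data: each 24 h array against the 0 h array of the other genotype, with random lists drawn for that difference, and list medians without saturated members. Chromosome positions were not used here, since the build behind the array annotation was not given. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.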

Results

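Gene expression was measured in mouse liver around an acetaminophen overdose, with and without YAP, a transcriptional coactivator of the Hippo pathway. Acetaminophen is converted in hepatocytes to a reactive metabolite that injures the liver. The study asks what YAP does while the liver regenerates after that injury. There were 4 arrays: wildtype at 0 h, YAP-KO at 0 h, wildtype at 24 h and YAP-KO at 24 h. Each held RNA pooled from 3 male fasted mice. No array of mice at 24 h without acetaminophen was among them. Effects of the overdose therefore cannot be told apart from those of time, handling or food intake between 0 h and 24 h. The word response stands for that whole difference. With 1 array per group there is no replicate check on any difference between arrays, so differences are described by size, in log2 units, over 18500 genes. The arrays correlated across genes (which are not independent replicates) at 0.9928 between the genotypes at 0 h, 0.9565 between wildtype times, 0.9847 between YAP-KO times and 0.9798 between the genotypes at 24 h.

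Yap1 (Entrez gene 22601) was lower in YAP-KO than in wildtype at both times. Its level was 7.54 in wildtype and 6.31 in YAP-KO at 0 h, a difference of -1.23, and 8.24 and 6.01 at 24 h, a difference of -2.23. The labels do not say which part of the gene is deleted or in which cells, so the probe set can read transcript that remains. Wwtr1, which encodes the YAP paralog TAZ, was 5.75 and 5.82 at 0 h and 6.73 and 6.35 at 24 h, in wildtype and YAP-KO. Ccn1 and Ccn2, matricellular protein genes used as readouts of YAP activity, were 8.39 and 5.73 in wildtype at 0 h against 14.11 and 9.48 at 24 h. In YAP-KO they were 7.44 and 5.79 at 0 h and 9.66 and 7.75 at 24 h. The probe set for Ccnd1 is annotated to a microRNA gene as well, and read 5.77 and 6.17 at 0 h and 6.81 and 7.08 at 24 h.

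**Figure D1:**
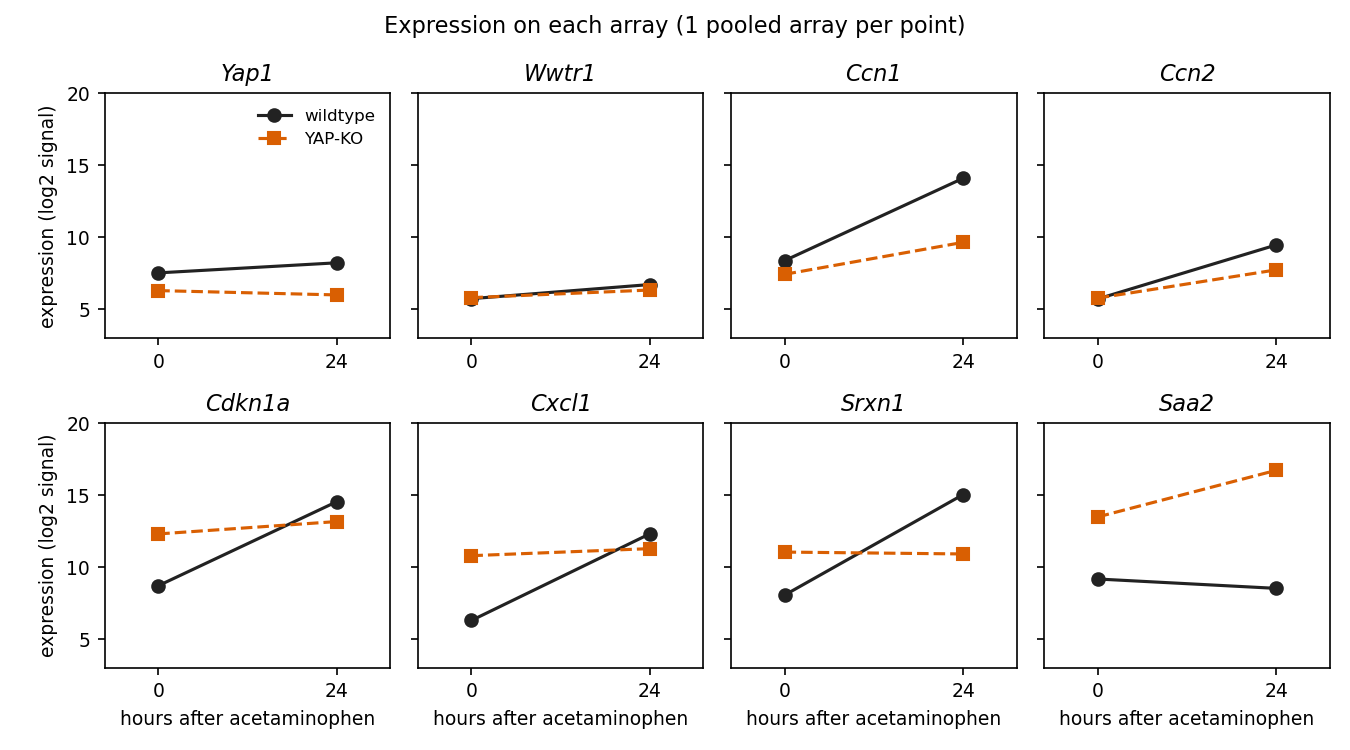
Expression (log2 signal, vertical axis) of 8 genes at 0 h and 24 h after acetaminophen (horizontal axis) in wildtype (black circles) and YAP-KO (orange squares), 1 pooled array per point and no error bars. Yap1 lies lower in YAP-KO at both times, Ccn1 reached 14.11 in wildtype against 9.66 in YAP-KO at 24 h, and Cdkn1a, Cxcl1, Srxn1 and Saa2 already lay higher in YAP-KO at 0 h.

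In wildtype liver, NRF2 target genes, neutrophil and monocyte markers, growth factor genes and YAP/TAZ target genes were higher 24 h after acetaminophen, and genes of bile acid handling, pericentral hepatocytes, lipogenesis and male-biased expression were lower. A total of 3428 genes differed 2-fold or more, 2341 higher and 1087 lower. The highest differences were those of Tnfrsf12a, the receptor of the cytokine TWEAK (8.01), Thbs1, encoding thrombospondin 1 (7.17), Srxn1, encoding sulfiredoxin (6.98), the vasodilator peptide gene Adm (6.73) and Lcn2, encoding lipocalin 2 (6.27). Metallothionein gene Mt2 was at least 6.35 higher, as its 24 h value is saturated. The keratin genes Krt18 (6.10) and Krt8 (6.04), the transcription factor gene Klf6 (6.08) and the glucose transporter gene Slc2a1 (6.05) followed. The lowest were Hsd3b5 (-7.84), a steroid dehydrogenase gene of male liver, the glutamate transporter gene Slc1a2 (-7.60), Nudt7 (-6.65), G6pc, the glucose-6-phosphatase gene (-6.60), Lpin1 (-6.50), the fatty acid elongase gene Elovl3 (-6.26), Oat, encoding ornithine aminotransferase (-6.23), Keg1 (-6.09), Hsd3b3 (-5.80) and Cyp2c38 (-5.64). With the mean of its probe sets Slc1a2 was -4.04, outside the 10 lowest values listed here.

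Of 14 measured NRF2 targets, 10 were at least 1.5-fold higher in wildtype at 24 h and 3 lower, with a median of 2.81 against a random range of -0.25 to 0.82. The heme oxygenase gene Hmox1 (5.29), the cystine transporter gene Slc7a11 (5.31) and the quinone reductase gene Nqo1 (4.43) stood beside Srxn1, while Gstm3 (-3.44), Gstm1 (-0.81) and Ephx1 (-0.62) went the other way. YAP/TAZ targets had a median of 0.89, with 12 of 21 higher and 0 lower, led by Ccn1 (5.72), Ankrd1 (4.57), Ccn2 (3.75) and Ajuba (3.31). Among growth factor genes (median 2.06, 8 of 10 higher), Jun (3.85), Myc (3.77), the EGF receptor ligand gene Ereg (3.29) and Btc (2.73) were highest and the receptor gene Egfr was lower (-1.66). Genes of G1/S had a median of 0.63, with 8 of 15 higher, among them Mcm6 (1.64), Pcna (1.36), Rrm2 (1.18) and Mcm3 (1.13). Of 18 fixed G2/M genes, 9 were below the expression filter and 2 had no probe set of their own. Of the 7 measured, 0 differed by 1.5-fold in either genotype. These 7 were dim, at 4.27 to 5.36 over the arrays with a filter level of 4.322. Without detection calls, their lack of change cannot be told from a lack of detection.

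In wildtype, neutrophil markers had a median of 2.52 (6 of 9 higher; 1.21 with no filter on dim genes), with S100a8 at 4.65 and Retnlg at 4.12, but Camp (-0.65) and Ly6g (-0.63) were lower. Monocyte and macrophage markers had a median of 1.56 (10 of 14 higher), led by Chil3 (5.22), Cd14 (4.66) and Cd68 (4.33). Haemoglobin probe sets, looked at after the data were seen, were higher too, those of alpha genes by 3.56 and 3.61 and those of beta genes by 2.17 and 2.47. Chemokines and cytokines (0.99; 0.54 with no filter, 2.25 with the 60th percentile filter), stellate cell and fibrosis genes (0.67, but Lrat -1.32), and integrated and endoplasmic reticulum stress genes (1.08, or 0.40 and inside it against the YAP-KO 0 h array, but Herpud1 -1.58) also lay above the random range, whereas the Kupffer cell list (0.83) lay inside it. Cxcl1, a neutrophil chemokine, was 6.02 higher, and the smooth muscle genes Tagln and Acta2 were 4.38 and 3.07 higher.

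Hepatocyte lists lay mostly below the random range in wildtype. Bile acid synthesis and transport genes had a median of -2.67, with 12 of 16 lower, including Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-5.46), Cyp7b1 (-4.56), the uptake transporter gene Slco1b2 (-4.37) and the bile salt export pump gene Abcb11 (-4.34), while the efflux transporter gene Abcc4 was higher (1.26). Pericentral genes had a median of -1.83 (9 of 11 lower, 0 higher), with Slc1a2, Oat, Cyp1a2 (-5.21) and Rgn (-4.75) lowest. The probe set of the pericentral gene Glul, annotated to a microRNA as well, not counted among the 11 and described after its values were seen, was -4.36. Periportal genes had a median of -1.02, with Hal at -4.16 and Pck1 at -2.43 but Cdh1, encoding E-cadherin, at 3.74 and Hsd17b13 at 0.61. Lipogenesis genes (-1.49, 8 of 9 lower, Thrsp -4.73), gluconeogenesis genes (-0.90; -0.53 against the YAP-KO 0 h array), male-biased genes (-2.50) and acetaminophen metabolism genes (-0.48, but Ugdh 1.17) were also below. Hepatocyte identity genes had a median of -0.31, but 6 of the 15 were saturated on all arrays, and without saturated members the median was -0.90. Cebpa (-2.43) and Nr1i3 (-2.27), both encoding transcription factors, were the lowest of that list.

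In YAP-KO liver fewer genes differed between the times: 1286 at 2-fold or more, 876 higher and 410 lower. The highest were Sprr1a (5.85), which was dim at 0 h, the macrophage genes Chil3 (5.61) and Cd68 (4.34), the acute phase gene Apcs (4.81), the matrix gene Tnc, which ranked between Cd68 and Cyp4a14, the fatty acid hydroxylase gene Cyp4a14 (3.92), Muc3 (3.92, but 1.77 with the mean of its probe sets), Thbs1 (3.86), Clec7a (3.84) and Dnajc12 (3.77). Lowest were Rgs16 (-6.96), the pseudogene Glns-ps1 (-6.22), Slc1a2 (-6.06, but -3.21 with the mean of its probe sets), Elovl3 (-4.89), Mme (-4.19), Oat (-4.16), Cyp1a1 (-4.10), Etnppl (-3.74), Nudt7 (-3.66) and Gpcpd1 (-3.47). Cyp1a1 was high on the YAP-KO 0 h array alone (8.41, against 4.47 in wildtype at 0 h). Against the wildtype 0 h array, a comparison added after the data were seen, 1561 genes differed in YAP-KO at 24 h.

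Monocyte and macrophage markers in YAP-KO had a median close to that in wildtype, at 1.33, with 12 of 14 at least 1.5-fold higher at 24 h. Single markers differed: in the difference of responses 3 were at least 1.5-fold higher in YAP-KO and 3 lower. Male-biased genes (-2.52) and lipogenesis genes (-1.23; -0.68 against the wildtype 0 h array) were low in YAP-KO too, with Elovl3, Nudt7 and Cyp7b1 (-2.93) lowest in the male-biased list and Me1 (-2.63) lowest in the lipogenesis list. Bile acid (-1.16) and pericentral genes (-1.02) were lower at 24 h by less than in wildtype, and the bile acid transporter gene Abcc4 (0.92) and the pericentral gene Lect2 (0.87) were higher. The Glul probe set went the other way, at -5.68 in YAP-KO against -4.36 in wildtype, and so did the glutamine synthetase pseudogene Glns-ps1 (-6.22 against -4.89). Their levels were close on each array (8.59 for Glul and 8.54 for Glns-ps1 in YAP-KO at 24 h). The array may not separate the pseudogene from Glul, so these may not be separate observations. YAP/TAZ targets had a median of 0.36 in YAP-KO, above the random range (0.31 and above it against the wildtype 0 h array). Of 21 targets, 7 were higher, led by Ankrd1 (2.98), Ccn1 (2.22) and Ccn2 (1.96), and Igfbp3 was lower (-0.95). Cholesterol synthesis genes lay above the random range in YAP-KO (1.13, or 2.06 against the wildtype 0 h array), with 10 of 11 higher (Lss 2.12). In wildtype the cholesterol list lay inside its range at 0.49, or 0.04 after quantile normalization and 0.24 after centring. Against the YAP-KO 0 h array it was at -0.44 in wildtype, below the range. NRF2 targets had a median of 0.19, inside the random range, with 5 of 14 higher and Gstm3 (-1.89) and Gclc, the gene of a glutathione synthesis enzyme (-1.12), lower; against the wildtype 0 h array it was 0.73, above the range, with 8 of 14 higher and 1 lower. Growth factor genes (0.15; -0.01 with no filter) were inside it too, with Egfr (-1.13) and Myc (-0.63) lower, and neutrophil markers (0.44; 0.13 with no filter) above it. Stress genes (0.83, but Xbp1 fell from 13.49 to 12.49), chemokines and cytokines (0.49; 0.12 with no filter, 0.22 against the wildtype 0 h array) and stellate cell and fibrosis genes (0.50, but Reln -0.95) lay above the range, and acetaminophen metabolism genes (-0.36) and PPARA targets (-0.17) below it, at -0.54 and -0.45 against the wildtype 0 h array, whereas periportal (0.02) and gluconeogenesis genes (0.05; -0.33 without saturated members) lay inside, but both were at -0.66, below the range, against the wildtype 0 h array. Hepatocyte identity genes had a median of 0.02, below the range, which was -0.28 after quantile normalization, -0.12 after centring, -0.50 without saturated members and -0.01, inside the range, against the wildtype 0 h array; Hnf4a (-1.45), Cebpa (-1.28), Nr1i3 (-0.84) and Fabp1 (-0.80) were lower. Genes of G1/S had a median of 0.37, above the random range as in wildtype, with 14 of 15 above 0. At least 1.5-fold higher were 4 of 15, among them Mcm6 (1.35), and Rrm2 was lower (-0.65). Between the genotypes the G1/S median was -0.14 at 24 h and -0.16 for the difference of responses, both inside the random range.

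**Figure D2:**
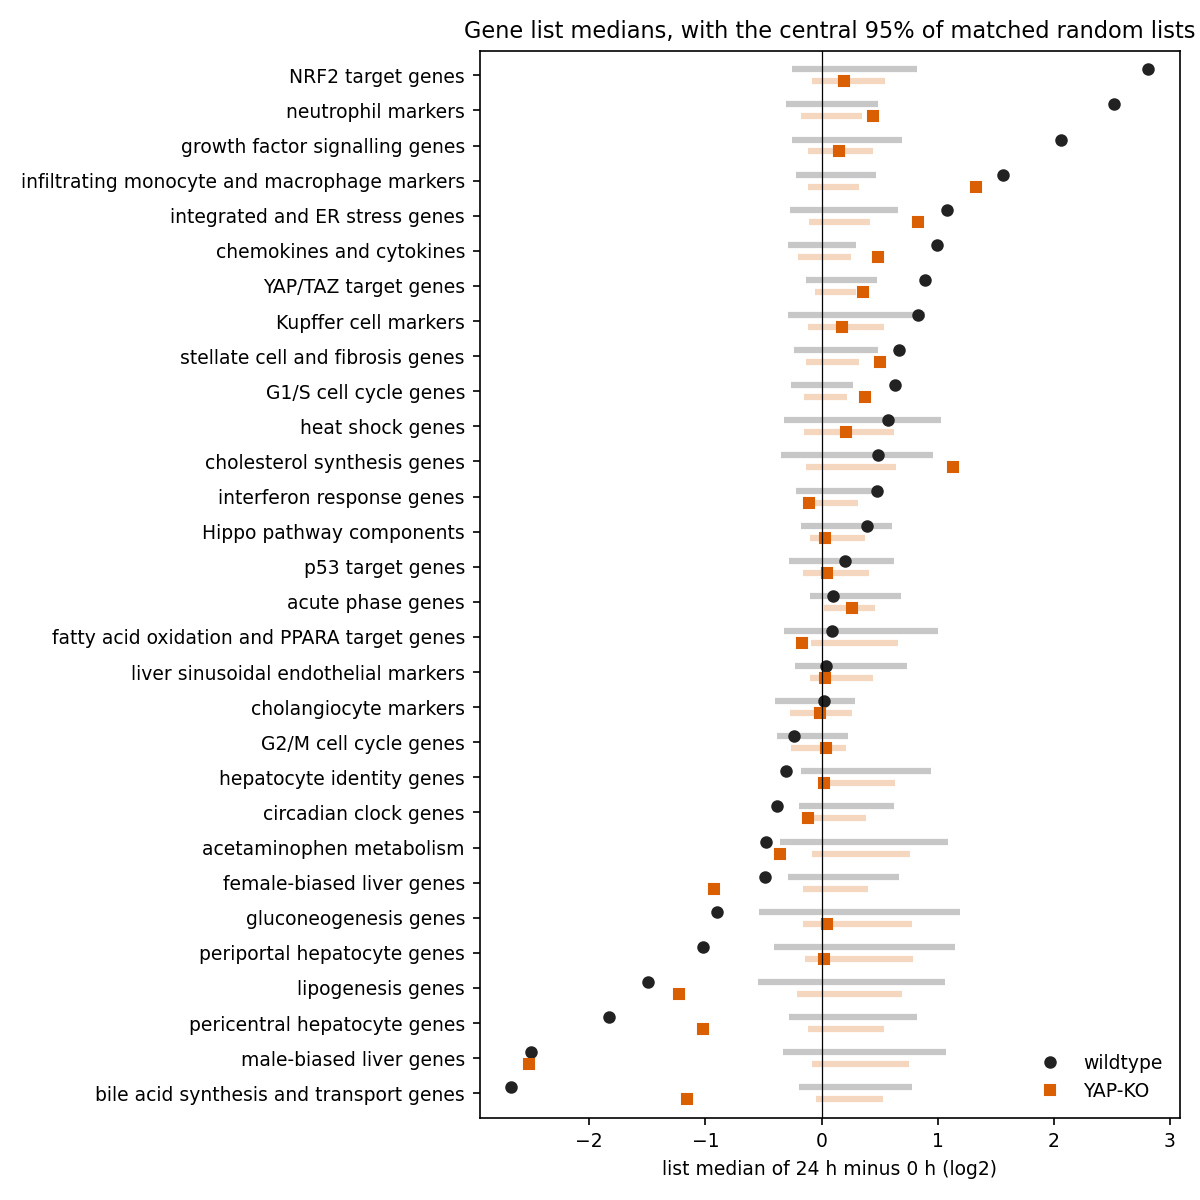
Median difference between 24 h and 0 h (log2, horizontal axis) of each gene list with at least 5 measured members (vertical axis) in wildtype (black circles) and YAP-KO (orange squares), 1 array per group and time. Pale bars span the central 95% of random lists matched on expression; NRF2 targets lie at 2.81 in wildtype and 0.19 in YAP-KO, while monocyte and macrophage markers lie at 1.56 and 1.33.

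The genes that differed between 24 h and 0 h overlapped between the genotypes. Of the genes 2-fold higher in YAP-KO, 538 were also 2-fold higher in wildtype, where independent lists would share 111, and 231 were lower in both, where 24.1 would be shared. Across all 18500 genes the 2 responses, which share no array, correlated at r = 0.565 (rho = 0.507), genes not being independent replicates. Among the 3917 genes 2-fold in either genotype, 83% had the larger difference in wildtype and 85% had the same sign in both. The 83% follows largely from the counts at 2-fold. A gene 2-fold in wildtype alone has the larger difference there by definition. Genes 2-fold higher in wildtype, with a median of 1.45 there, had a median of 0.54 in YAP-KO. Picking genes on the wildtype value favours a larger wildtype median; genes picked as 2-fold higher in YAP-KO had medians of 1.26 in YAP-KO and 1.25 in wildtype.

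**Figure D3:**
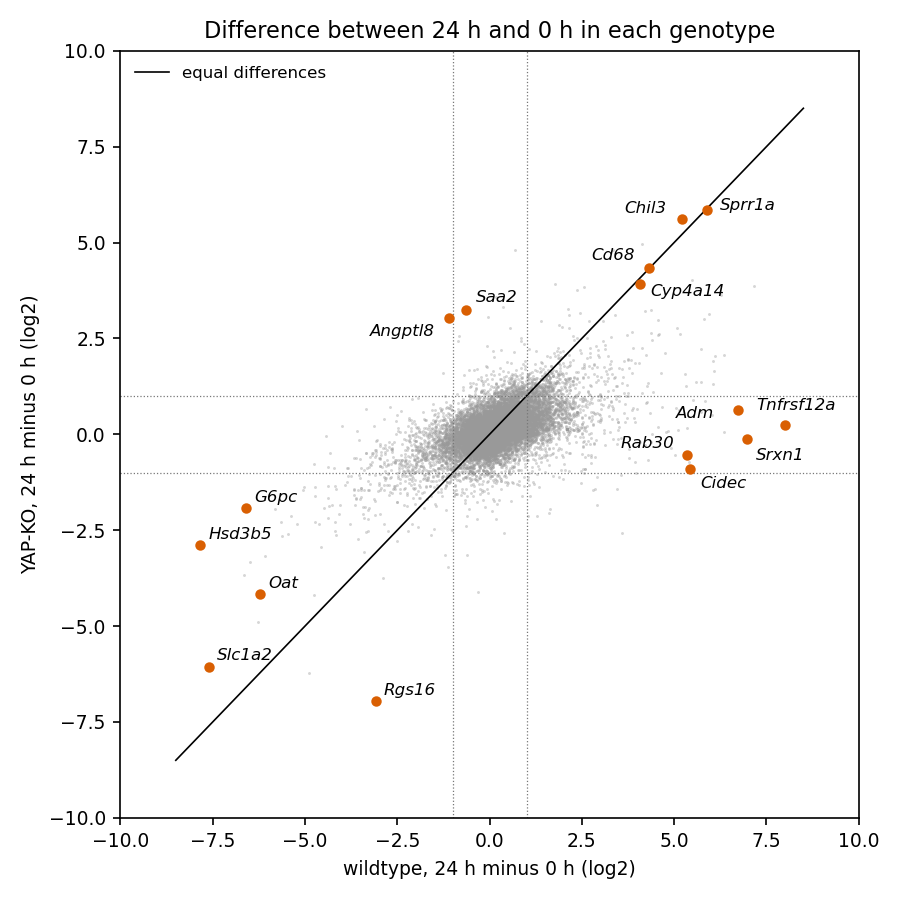
Difference between 24 h and 0 h (log2) of each of 18500 genes in wildtype (horizontal axis) and YAP-KO (vertical axis), 1 array per group and time, with 16 genes named; dotted lines mark 2-fold and the diagonal marks equal differences. Cd68, Chil3, Sprr1a and Cyp4a14 lie near the diagonal, and Tnfrsf12a, Srxn1 and Adm lie far below it, at 8.01, 6.98 and 6.73 in wildtype against 0.25, -0.13 and 0.64 in YAP-KO.

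Before acetaminophen, 350 genes differed 2-fold or more between the genotypes, 188 higher and 162 lower in YAP-KO. The balance turned with the size of the difference: at 1.5-fold 639 were higher and 901 lower, and at 4-fold 38 and 6. On the higher side Mt2 was at least 6.25 higher, as its YAP-KO value is saturated, followed by Mt1 (4.69), Cxcl1 (4.50), the serum amyloid genes Saa2 (4.31) and Saa1 (3.97), Cyp1a1 (3.94), the interleukin 1 receptor gene Il1r1 (3.64), the cell cycle inhibitor gene Cdkn1a (3.60), Tnfrsf12a (3.35) and Steap4 (3.31). On the lower side were Dmbt1 (-4.15), Cyp4a14 (-2.82), the glycogen-targeting subunit gene Ppp1r3c (-2.08), Etnppl (-1.88), the lipase gene Lipg (-1.79) and 5 major urinary protein pseudogenes between -2.04 and -1.75, whose near-identical copies the array may not separate. The lists above their random range were acute phase (median 0.26, 7 of 21 higher), NRF2 targets (0.42, 6 of 14 higher), p53 targets (0.35, 5 of 12 higher), integrated and endoplasmic reticulum stress (0.30, 5 of 13), heat shock (0.30, or 0.56 without saturated members, 4 of 9), interferon response (0.32, 3 of 13), neutrophil markers (0.22, or 0.04 with no filter, 1 of 9), cholesterol synthesis (0.74, 7 of 11) and lipogenesis (0.18, 2 of 9, with Thrsp at -0.82). The endoplasmic reticulum gene Creld2 was 2.75 higher and Xbp1 was 1.82 higher. PPARA target and fatty acid oxidation genes (-0.65, 6 of 11 lower), gluconeogenesis genes (-0.50, 3 of 7 lower), circadian clock genes (-0.28) and monocyte markers (-0.20) lay below. In the PPARA list Acot1 (-1.47) and Vnn1 (-1.35) followed Cyp4a14, and Pdk4 was higher (0.69). YAP/TAZ targets had a median of 0.00, with 0 higher and 1 lower by 1.5-fold, Ccn1 (-0.95).

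At 24 h, 1658 genes differed 2-fold or more between the genotypes, 598 higher and 1060 lower in YAP-KO. Of the serum amyloid genes, Saa2 was 8.20 and Saa1 7.36 higher in YAP-KO, while Saa3, named after its value was seen, was 0.62 higher. Saa4 was 3.60 higher, with a 24 h response of -3.55 in wildtype and -0.15 in YAP-KO, and the orosomucoid gene Orm2 was 3.50 higher; Saa1 and Saa2 are close paralogs whose signals can overlap. Also higher were Serpina4-ps1 (4.47), Angptl8, encoding an inhibitor of triglyceride clearance (4.45), Hsd3b5 (4.28), Rgn (3.65), G6pc (3.51) and Serpina7 (3.49). The lower side held Rab30 (-6.14), Adm (-5.78), the lipid droplet genes Cidec (-5.59) and Hilpda (-4.60), the phosphatase gene Dusp5 (-4.97), Slc2a1 (-4.47), Ccn1 (-4.45), Ivl (-4.45), Tnfrsf12a (-4.41) and Sult1e1 (-4.35).

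YAP/TAZ targets had a median of -0.52 in YAP-KO against wildtype at 24 h, with 9 of 21 lower and Nuak2 higher (0.67). Ajuba (-2.59), the tissue factor gene F3 (-2.13) and Ccn2 (-1.73) followed Ccn1. NRF2 targets (-1.66) had 9 of 14 lower, with Srxn1 (-4.12), Slc7a11 (-4.10), Gclc (-3.10) and Nqo1 (-3.05), against Gstm3 (2.45) and Gstm1 (0.82). Growth factor genes (-1.28, 7 of 10 lower, Myc -2.87, but Egfr 1.72), neutrophil markers (-1.63, 6 of 9 lower; -0.78 with no filter), chemokines and cytokines (-0.35; -0.12 with no filter), Kupffer cell markers (-0.56, but C6 2.11 and Slc40a1 0.59) and female-biased genes (-0.44, but Cyp3a44 0.77) were below the random range as well. Haemoglobin probe sets were lower as well, at -2.50 and -2.52 for alpha genes and at -1.73 and -1.88 for beta genes. Monocyte and macrophage markers (-0.03) lay inside the random range, with Cd14 at -3.73 and Ly6c2 at 0.97. PPARA target genes had a median of -2.16, with 7 of 11 lower, among them Pdk4 (-4.25), Angptl4 (-3.36), Cyp4a14 (-2.98) and the lipid droplet gene Plin2 (-2.77), while Ppara itself was 0.83 higher. Cholesterol synthesis genes (1.57, 10 of 11 higher), lipogenesis genes (0.79, but Me1 -0.84), bile acid genes (1.46, 11 of 16 higher, but Abcc3 -1.44), pericentral genes (1.02, 7 of 11 higher, 0 lower), male-biased genes (1.21, but Cyp4a12a -0.94 and Cyp4a12b -0.93) and acute phase genes (0.41, 9 of 21 higher; 0.62 without saturated members, 0.63 after quantile normalization) lay above. The Glul probe set (-1.65) and Glns-ps1 (-1.75), which the array may not separate, were lower. In the cholesterol list Fdps (2.46), Hmgcs1 (2.02), Insig1 (1.98) and Dhcr7 (1.85) were highest.

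The 24 h responses of 2433 genes differed 2-fold or more, 1047 with the higher value in YAP-KO and 1386 with the lower. The lowest, YAP-KO minus wildtype response, were Tnfrsf12a (-7.76), Srxn1 (-7.11), Cidec (-6.32), Ppl (-6.17), Tubb2a (-6.13), Adm (-6.09), Rab30 (-5.87), Chka (-5.57) and Cxcl1 (-5.53). Mt2 ranked among them but is left out, as it was saturated on every array except wildtype at 0 h. Tnfrsf12a, Srxn1, Cidec, Ppl, Tubb2a, Chka and Cxcl1 were already higher in YAP-KO at 0 h, by 3.35, 2.99, 0.73, 3.29, 2.65, 2.08 and 4.50, whereas Adm (0.31) and Rab30 (-0.27) were not 1.5-fold different then. The highest were Hsd3b5 (4.95), G6pc (4.67), Dmbt1 (4.38), Ppp1r3b (4.21), Angptl8 (4.15), Ppp1r3c (4.01), Rgn (3.98), Saa2 (3.89), Hsd3b3 (3.85) and Aox3 (3.83). Cdkn1a was 8.70 in wildtype and 12.30 in YAP-KO at 0 h, and 14.54 and 13.16 at 24 h. The genotype differences at 0 h and at 24 h, which share no array, correlated across genes at r = -0.100, with 31 genes 2-fold higher at both times (6.08 by independent lists) and 20 lower at both (9.28 by independent lists).

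Over both genotypes, 0 of 18500 genes passed limma's adjusted p under 0.05 for 24 h against 0 h, with a smallest adjusted p of 0.283, and 2840 had an unadjusted p under 0.05, 2103 higher and 737 lower. Smallest p-values belonged to genes with like differences in both genotypes: Sprr1a (5.88 ± 0.172, SE), Chil3 (5.42), Cd68 (4.33), Tnc (4.05), Cyp4a14, Mme (-4.47), Acta2 (3.02), Akr1b8 (3.26) and Ugt2b1 (-3.23). For YAP-KO against wildtype over both times 0 genes passed limma's threshold, with a smallest adjusted p of 0.997, and 438 had an unadjusted p under 0.05, 158 higher and 280 lower. Cyp4a14 (-2.90 ± 0.177, SE), Creld2 (2.57), Syvn1 (2.10), Lrg1 (1.75), Acot1 (-1.57), Cyp4a32 (-1.67) and Fam13a (-1.84) were among the 10 smallest p-values, and Yap1 had a difference of -1.73 ± 0.33 (SE, adjusted p of 0.997).

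No list had a member past the threshold over all genes tested. Adjusting p over a list alone leaves the number of lists (32) and factors (2) uncorrected, so the counts below are descriptive. With limma's p adjusted over the list alone, 7 of 14 monocyte and macrophage markers rose at 24 h (Cd68 and Chil3 among them), and so did 6 of 13 stress genes, 4 of 14 stellate cell and fibrosis genes, 3 of 21 acute phase genes, 3 of 11 cholesterol synthesis genes, 2 of 11 chemokines and 2 of 10 growth factor genes. By that measure 7 of 11 male-biased, 6 of 11 pericentral, 6 of 9 lipogenesis, 4 of 16 bile acid and 2 of 9 periportal genes fell, and Egfr fell in the growth factor list. Abcc4 of the bile acid list rose. Of 14 circadian genes 3 fell and 1 rose, and of 8 female-biased genes 1 fell and 1 rose. The heat shock, Kupffer cell and PPARA lists had 1 gene each that rose. Alas2 fell, but it was the only measured gene of its list, so its p was in effect unadjusted. Adjusted over the list alone for genotype, 5 of 11 cholesterol synthesis genes were higher in YAP-KO (Hmgcs1, Sqle, Idi1, Lss and Cyp51), Creld2 was higher in the stress list, and 3 of 11 PPARA targets (Cyp4a14, Vnn1 and Acot1) were lower; these genes were named after their values were seen. For YAP/TAZ targets, NRF2 targets, G1/S genes and neutrophil markers 0 genes passed for either factor. At an unadjusted p under 0.05 for time there were 6, 4, 5 and 3. Genes that respond differently in the genotypes have large errors in this fit, so 0 passing does not show a lack of change.

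The balance of higher and lower genes depends on how the arrays are scaled. The median tested gene was 6.44 on both 0 h arrays, 6.69 in wildtype at 24 h and 6.58 in YAP-KO at 24 h. Centring the arrays on it lowers every 24 h difference by 0.25 in wildtype and 0.14 in YAP-KO. These shifts exceed the median difference over genes, which was 0.07 in both genotypes. Medians over all probe sets moved the other way, from 4.47 to 4.32 in wildtype and from 4.46 to 4.36 in YAP-KO. The values after centring therefore depend on which median is taken. The share of 2-fold genes that were higher at 24 h was 68.3% in wildtype and 68.1% in YAP-KO as deposited, 57.8% and 58.9% after quantile normalization, and 49.1% and 50.9% after centring. For YAP-KO against wildtype at 24 h it was 36.1%, 48.6% and 47.4%, and for the difference of responses 43.0%, 50.6% and 54.0%. Among genes with an unadjusted p under 0.05 for time, the split of 2103 higher and 737 lower became 1679 and 944 after quantile normalization and 1334 and 1368 after centring.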

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

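All tests of explanations in this part were chosen after the results were seen, except the test of a narrower signal range, which was written down before its value was known. Tests of a milder injury of the YAP-KO pool, and of injured liver in the YAP-KO 0 h pool on lists that were low after acetaminophen, are left out, because their bounds were revised after the values were seen.

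The 84 genes named for themselves, by rank in a contrast or by p-value were compared, without those named only as list members. Of these 84 genes, 8 were at least 1.5-fold higher at 24 h in one genotype and 1.5-fold lower in the other. These differences between the genotypes were not tested, since each rests on 4 single arrays. Saa2 was 3.24 higher in YAP-KO and -0.65 in wildtype, Saa1 2.56 and -0.83, Angptl8 3.04 and -1.11, and Ppp1r3c 0.67 and -3.34. In the opposite direction, Ppl was -2.58 in YAP-KO and 3.59 in wildtype, Il1r1 -2.05 and 1.60, Cidec -0.90 and 5.42, and Tubb2a -0.73 and 5.40. Several of these rest on the YAP-KO 0 h array. From wildtype 0 h to YAP-KO 24 h, Ppl went from 6.45 to 7.16, Il1r1 from 12.04 to 13.63 and Tubb2a from 10.41 to 12.33, upward as in wildtype. Ppp1r3c went from 11.38 to 9.97, downward as in wildtype, and Cidec from 5.57 to 5.40, less than 1.5-fold. Saa2, Saa1 and Angptl8 stayed opposite with that baseline. Over all 18500 genes, 151 met the same measure, 98 of them higher in wildtype. They include genes named only as list members, such as Gclc (2.91 in wildtype and -1.12 in YAP-KO) and Ugdh (1.17 and -1.25). Slc40a1 (-0.69 and 0.67) went the other way. With each genotype's own 0 h array, no gene list lay outside its random range on opposite sides in the genotypes.

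The first pattern is that fewer genes differed 2-fold between 24 h and 0 h in YAP-KO (1286) than in wildtype (3428). A shifted YAP-KO 0 h array as the whole cause is argued against: with the wildtype 0 h array as the baseline, the YAP-KO 24 h array gave 1561 genes, 45.5% of the wildtype count. A narrower signal range of the YAP-KO 24 h array is argued against too, since after quantile normalization, which gives all arrays one range, the YAP-KO count was 37.3% of the wildtype count. A milder injury of the YAP-KO pool stays open, as injury was not measured. Loss of YAP and a difference between 2 pools of mice cannot be told apart here, as each genotype has 1 pool at 24 h.

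The second pattern is the high stress and acute phase genes of the YAP-KO 0 h array. An exchange of the YAP-KO 0 h and 24 h arrays is argued against, since the pericentral list of the 0 h array was -0.08 against wildtype 0 h, inside its random range, and that of the 24 h array was -1.10. Liver like that of 24 h among the animals of the YAP-KO 0 h pool is argued against as the cause for the set. Taking signal as proportional to share, the 12 acute phase and stress genes at least 1.5-fold higher at 0 h would need a median share of 39.3% of such liver. That share would put the monocyte and macrophage list, which was high at 24 h in both genotypes, at 0.47. The list was at -0.20, below its random range. Cd68 would be at 3.07 and was -0.03, and Chil3 at 3.89 and was -0.43. These 2 had the largest expected values of the 14 markers. Adgre1 (0.06), Gpnmb (0.05) and Cx3cr1 (0.00), named after their values were seen, were expected to change too little to tell. The shares needed ran from 6.82% (Sdf2l1) to 269% (Steap4), and Steap4 (by 1.20), Xbp1 (by 0.74) and, barely, Saa3 (by 0.03) exceeded both 24 h arrays; at the lowest share the list would be at 0.09. An injury or illness of another kind or stage stays open, since no array here shows one, as does an effect of YAP loss, which was not tested separately.

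The third pattern is that PPARA target genes were lower and cholesterol synthesis genes higher in YAP-KO at 24 h. At 0 h, before the overdose, the cholesterol list was already 0.74 higher and the PPARA list was -0.65, both outside their random range. Food intake after the overdose cannot account for these 0 h differences. The 24 h arrays are of other pools of mice, so whether those pools began with the same differences is not known. The difference between the 24 h responses was outside its random range for the cholesterol list (0.69, 99.54 percentile) and inside it for the PPARA list (-0.42, 4.645 percentile). The PPARA list was at -2.16 at 24 h, however. Its response differences had a mean of -1.15, with 5 of 11 members at least 1.5-fold lower and 1 higher. For the 24 h differences, in whole or in part, food intake stays open. The gluconeogenesis list, which fasting raises, had a median of 0.27 in YAP-KO against wildtype at 24 h, inside its random range (92.92 percentile), with members going both ways (G6pc 3.51, Pck1 1.77, Got1 -1.24). Genotype remains among the open explanations.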

How the results depend on the processing

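The use of the other genotype's 0 h array and the removal of saturated genes were chosen after seeing the data; the others were planned. The counts at 2-fold stayed within 1.5 times their value under quantile normalization, centring, both filters and the mean of probe sets, and with the other genotype's 0 h array (3115 genes for wildtype, 1561 for YAP-KO). The size threshold moved them, as it sets what is counted: at 1.5-fold and 4-fold they were 6520 and 880 for wildtype at 24 h against 0 h, 3615 and 150 for YAP-KO at 24 h against 0 h, 1540 and 44 for the genotypes at 0 h, 4007 and 356 for the genotypes at 24 h, and 5588 and 454 for the difference of responses. Under every alternative to limma's fit 0 genes passed for time or genotype, with 2144 to 3926 and 260 to 821 genes at an unadjusted p under 0.05. Of 499 alternative values for list medians outside their random range, 444 were within 1.5 times the reported value, 50 moved further with the same sign and 5 reversed. Besides those given with the results, with no filter p53 targets at 0 h were 0.23, and female-biased genes -0.28 in wildtype, -0.40 in YAP-KO and -0.17 between the genotypes at 24 h. With the 60th percentile filter G1/S genes were 1.10 in wildtype, chemokines 1.33 and neutrophil markers 0.92 in YAP-KO, p53 targets 0.65, stress genes 0.56 and acute phase genes 0.16 at 0 h, and female-biased genes -0.83 at 24 h. Centring gave, in wildtype, 0.38 for G1/S, 0.42 for stellate cell, -0.73 for acetaminophen metabolism, -0.56 for hepatocyte identity, -0.63 for circadian and -0.74 for female-biased genes, and in YAP-KO 0.22 for YAP/TAZ targets, 0.23 for G1/S, -0.31 for PPARA and -0.27 for circadian genes. Quantile normalization gave -0.28 for PPARA and -0.21 for circadian genes in YAP-KO. With the other genotype's 0 h array, gluconeogenesis (-0.53) and circadian genes (-0.23) moved in wildtype, and chemokines (0.22), acetaminophen metabolism (-0.54), PPARA (-0.45), lipogenesis (-0.68), cholesterol (2.06) and circadian genes (-0.51) in YAP-KO. Of 64 list medians at 24 h against 0 h, 10 changed their side of the random range with that array: stress, endothelial (-0.25), PPARA (1.22) and cholesterol genes (-0.44) in wildtype, and NRF2 (0.73), periportal (-0.66), gluconeogenesis (-0.66), acute phase (0.84), heat shock (0.71) and hepatocyte identity genes in YAP-KO. Without saturated genes acetaminophen metabolism was -0.60 and acute phase genes 0.71 in YAP-KO. The hepatocyte identity list in YAP-KO at 24 h against 0 h, 0.02 as reported, was -0.28 after quantile normalization, -0.12 after centring, -0.50 without saturated genes and -0.01 with the wildtype 0 h array as baseline; 6 of its 15 members are saturated, and the cause was not tested. The female-biased list in wildtype, -0.49 as reported, was 0.28 with the 60th percentile filter, which leaves fewer members. Of 595 alternative values for named genes, 589 were within 1.5 times the reported value and 0 reversed; the 24 h response of Yap1 in wildtype, 0.70 as deposited, was 0.46 after quantile normalization and 0.45 after centring. No paired analysis was possible because the groups share only the replicate number 1. Leaving out a replicate was not run, since each group has 1 array and the limma fit would keep 0 residual degrees of freedom. Without detection calls, differences of dim genes are likely understated to an unknown extent, and saturation limits those of the brightest 82 genes.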

Other observations

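Other groups of genes in the arrays are given as values. The list of liver sinusoidal endothelial markers lay inside the random range at 24 h (medians of 0.04 in wildtype, or -0.25 and below it against the YAP-KO 0 h array, and 0.03 in YAP-KO), but the hyaluronan receptor gene Lyve1 was 5.51 higher in wildtype and 0.89 higher in YAP-KO, and Cdh5, encoding VE-cadherin, was 3.23 and 1.70 higher. The probe sets that are each annotated to 2 haemoglobin alpha genes read 9.85 and 10.35 in wildtype at 0 h, 13.41 and 13.96 in wildtype at 24 h, and 10.91 and 11.44 in YAP-KO at 24 h. Alas2, the erythroid heme synthesis gene and the only erythroid gene measured alone, went the other way, at -2.24 in wildtype and -1.86 in YAP-KO. Cholangiocyte markers had medians of 0.02 and -0.01, with Sox9, a transcription factor gene of bile ducts, at 2.53 and 1.47. Of 13 lymphocyte markers, 3 passed the filter, with medians of -0.17 and -0.03.

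Circadian clock genes lay below the random range at 24 h against 0 h in both genotypes (-0.38 in wildtype, or -0.63 after centring and -0.23 against the YAP-KO 0 h array; -0.12 in YAP-KO, or -0.21 after quantile normalization, -0.27 after centring and -0.51 against the wildtype 0 h array). Dbp was -2.05 in wildtype and -1.29 in YAP-KO, Nr1d1 was -1.50 and -2.47, while Per1 was 2.03 and 0.39 and Cry1 was 0.99 and 0.93. The hour of the day at which livers were taken was not given in the sources used here. Female-biased liver genes had medians of -0.49 in wildtype, which was 0.28 with the 60th percentile filter, and -0.93 in YAP-KO. Of their 8 measured members 3 were at least 1.5-fold higher in wildtype, Abcd2 (2.69), Cyp17a1 (1.52) and Acot3 (0.85), and 1 in YAP-KO, Abcd2 (2.95). Among Hippo pathway components, whose medians of 0.39 and 0.03 lay inside the random range, the TEAD transcription factor gene Tead1 was 2.58 higher in wildtype and 0.16 in YAP-KO. Interferon response genes (0.48 and -0.11), p53 targets (0.20 and 0.05), acute phase genes (0.10 and 0.26) and heat shock genes (0.57 and 0.21) lay inside the random range at 24 h in both genotypes. Rsad2 was at 3.48 in wildtype and -0.11 in YAP-KO. Of 21 acute phase genes, however, 6 were saturated on at least 1 array. In YAP-KO 9 of the 21 were at least 1.5-fold higher and 1 lower. Their YAP-KO median was 0.71 without saturated members and 0.58 with the 60th percentile filter, where the reported random range ended at 0.46. In wildtype it was 0.17 and 0.10. Against the wildtype 0 h array the YAP-KO medians were 0.84 for acute phase genes (13 of 21 higher, 0 lower) and 0.71 for heat shock genes (6 of 9 higher), both above the range, and 0.26 for interferon and 0.21 for p53 genes, inside it; these 4 lists already lay above their random range on the YAP-KO 0 h array against wildtype.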
